A study of Mus musculus with 6 samples.

How the data were processed

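Total RNA from laser-microdissected crypts of 6 mice was labelled with Cy3 and hybridised against Universal Mouse Reference RNA, a pool from cultured cell lines, labelled with Cy5, per the labels. Each array held 1 mouse and dyes were not swapped, so a dye effect of a gene is shared by both groups. Spot intensities of both channels were deposited by the authors as written by Agilent Feature Extraction A.7.5.1, per the file headers. The headers describe the mean signal and the median local background as unnormalized intensity. The processed signal is the intensity after background subtraction and LOWESS dye normalization, per the file headers. A deposited table of log10 values was also used as an alternative. It matched log10 Cy3 minus log10 Cy5 processed signal plus the mean log10 Cy5 over arrays, with r of 0.998 or more on each array across 41174 features, so its scale, centring and direction were known, and the median of each of its 6 columns was 2.90. How the authors tested the groups is not given in the sources used here.

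Each array had 43430 features, of which 41034 were not controls, for 41006 probes. Probe names were set against a reference gene table of GRCm38.p6 by accession or synonym. It gave a gene symbol to 15406 probes (37.6%), for 12340 symbols, and left 25600 probes unnamed here. A total of 2807 symbols had more than 1 probe, and the probe of highest mean Cy3 signal was used. The order of genes along the chromosome of Igf2 was taken from the table to pick its neighbours. Of 1071 list members written, 826 had a probe.

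The mean signals were background-corrected in limma 3.58.1 (R 4.3.3) with normexp and an offset of 50, and normalized by loess within each array with control features at weight 0. Features marked as outliers were left out and saturated ones kept. Values are log2 of Cy3 over Cy5, with spots of a probe averaged. The planned filter, Cy3 well above background on at least 3 arrays, removed 0 probes, so it had no effect. By comparison, 95.6% of probes lay above the 95th percentile of the 314 negative control features on 3 or more arrays. Groups were compared with lmFit and eBayes and Benjamini-Hochberg adjustment over 37940 genes and unnamed probes, two-sided, at 0.05. The median SE of a log2 difference was 0.077.

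A total of 31 gene lists of at least 5 measured genes (cell type markers, pathways and complexes), written from textbook knowledge, were tested with camera at a preset correlation of 0.01 against the 12260 named genes with a value on every array, with camera at an estimated correlation and with fry. Main tests, lists and most alternatives were fixed before the data were examined. The named genes were Igf2, Igf2r and Insr with H19 and Igf1r, then the 12 genes per direction with the largest difference past the threshold, filled up with those of smallest p whose arrays did not overlap, and the 4 members of smallest p of each called list and of the DNA replication, mitosis, G1/S regulation, crypt stem cell and Paneth cell lists. Some genes that this rule or a count would name are not reported here. The erythrocyte list had too few measured genes to be tested. The mice are separate animals per the labels. The alternatives covered background correction, normalization, the values used, filters, probes per gene, model, replicate block, sex label and leaving out each array, and further ones were added after seeing the data. A block for scan date was not run, because no scan date was used here. Image extraction fell on 1 day, with the LOI(-) arrays first, so extraction order and group cannot be told apart.

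The tests were run on simulated data first, over 37600 genes with the spread of the real arrays and genes independent of each other. For the comparison of LOI(+) with LOI(-), 50 genes changed by 0.5 were recovered at 50%, 50 changed by 1 at 86%, 50 changed by 2 at 100% and 50 changed by 3 at 98%, with 6 false calls. All of these genes were changed in the same simulated data, where the larger changes loosen the adjusted threshold for the smaller. The 50% therefore need not hold where few genes change. A simulated list of 47 genes shifted by 0.27 among 12300 simulated genes was called and 0 of 19 unshifted lists were. Those simulated genes were not correlated, unlike the real lists.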

Results

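Gene expression was measured in crypts, the glands at the base of the intestinal lining that hold its dividing progenitor cells. The crypts were cut by laser microdissection from the middle of the small intestine of 6 mice aged 120 days. The LOI(+) group of 3 mice had inherited from the mother a deletion of the H19 gene and its upstream control region. Per the series' design, that deletion switches on the maternal copy of Igf2, a fetal growth factor gene, which is silent in the 3 wild-type LOI(-) mice. Each mouse had its own 2-colour array, with mouse RNA in the Cy3 channel and the same pooled reference RNA in the Cy5 channel. The median Cy3 signal of a feature lay between 552 and 603 on the 6 arrays, over a median local background of 387 to 391. The log2 ratios correlated between arrays, across genes, with r from 0.932 to 0.975. LOI(+) 2 had the lowest mean r with the other arrays, 0.948, and the most features marked as outliers, 146. Differences are given as LOI(+) minus LOI(-) on the log2 scale with their standard error (SE), n = 3 mice per group, so the number of arrays limits the precision.

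The targeted region was read first. Igf2 had a log2 ratio of 0.092 ± 0.064 (SD, n = 3) in LOI(-) crypts and 0.089 ± 0.020 (SD, n = 3) in LOI(+) crypts. The difference was -0.0026 ± 0.057, with an adjusted p of 0.996 in limma and a 95% interval from -0.14 to 0.13. Its Cy3 signal was low, between 622 and 728 on the 6 arrays, against 439 to 449 at the 95th percentile of the negative control features. H19 and Igf1r were not analysed here, because no probe was paired with either name, so the group labels were not checked by the deleted gene. Igf2r, the receptor that clears IGF2, differed by 0.063 ± 0.091, and Insr, the insulin receptor, by -0.044 ± 0.080, neither past the test. Among imprinted genes near Igf2, Kcnq1 differed by 0.32 ± 0.10, Cdkn1c, a cell cycle inhibitor, by 0.16 ± 0.059, Slc22a18 by 0.13 ± 0.14, Ins2 by -0.0069 ± 0.056 and Phlda2 by -0.062 ± 0.18. None of these 5 passed the test, and they were chosen after their values were seen.

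The crypts were dissected to read the dividing progenitor cells, and genes of DNA replication rose as a list in LOI(+) crypts. With a preset correlation of 0.01 between genes the list had an adjusted p of 2.05e-17 by camera, and with the estimated correlation of 0.380 the adjusted p was 0.513. Of 47 measured replication genes, 43 had a higher mean in LOI(+), and the list differed by 0.27 ± 0.086 (SE over arrays), a fold of 1.21. Adjusted over the list alone, 19 members rose and 0 fell, while 0 passed over all genes tested in limma and 22 passed at an unadjusted p under 0.05. Among the 19 were Mcm5, a subunit of the replicative helicase, at 0.54 ± 0.087, Chaf1a, which places histones on new DNA, at 0.55 ± 0.089 and Cdc6, which loads the helicase, at 0.45 ± 0.089. Pcna, the sliding clamp of the polymerases, was at -0.078 ± 0.087 and was chosen after its value was seen. The list means of the arrays, centred on their mean, did not overlap, at -0.20, -0.22 and 0.014 in LOI(-) and 0.052, 0.18 and 0.17 in LOI(+). An exact permutation test over the 10 splits of the arrays gave p = 0.1, two-sided, the smallest that 3 against 3 mice allow. The 148 pooled markers of villus enterocytes, fibroblasts, smooth muscle, endothelium, B, T and myeloid cells had a median of -0.049. That pool left out goblet and Paneth cell markers. Genes of the upper small intestine were higher in LOI(+) than those of the lower by 0.58. Of those 30 genes, 13 were chosen after their values were seen, and the others gave 0.37. With the index of all 30 as a covariate, added after seeing the data, the replication list stood at 0.27 ± 0.16.

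Mitosis genes also rose as a list, by 0.18 ± 0.12, with 33 of 35 higher in LOI(+). Unlike for replication, the list means of the arrays overlapped, with LOI(-) 3 at 0.084 and LOI(+) 1 at -0.055. The mitosis genes had an adjusted p of 5.20e-06 by camera, and with an estimated correlation the adjusted p was 0.513. Adjusted over the list alone 0 members passed, and 5 passed at an unadjusted p under 0.05, all higher. Birc5, a survival factor of the chromosomal passenger complex, was at 0.62 ± 0.23 and Tpx2, a spindle assembly factor, at 0.34 ± 0.10. Without LOI(-) 2 the mitosis mean was 0.11, still called. Regulators of the entry into S phase had no common direction, and this list of 26 genes had a mean of 0.013 and an adjusted p of 0.964 by camera. The list holds both activators and inhibitors of that entry, so its mean cannot show whether the entry changed. Adjusted over that list alone, Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, fell by 0.73 ± 0.12 on the log2 scale and Ccne1, cyclin E1, rose by 0.55 ± 0.11. Another Ccne1 probe had the opposite sign, and neither gene passed over all genes tested.

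DNA repair genes rose as a list, by 0.10 ± 0.067, with 23 of 30 higher. This list had an adjusted p of 0.0268 by camera, and with an estimated correlation the adjusted p was 0.593. Adjusted over the list alone, Xrcc1, a scaffold of single-strand break repair, rose by 0.34 ± 0.082, Mre11a, a nuclease of double-strand break repair, rose by 0.35 ± 0.086, and Xrcc2, a factor of homologous recombination, fell by 0.23 ± 0.055, though its Cy3 signal was above the negative controls on 4 of the 6 arrays. The call was lost without LOI(-) 1, LOI(-) 2, LOI(+) 2 or LOI(+) 3, at 0.10, 0.069, 0.065 and 0.088, and without LOI(+) 1 the mean was 0.15.

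**Figure D1:**
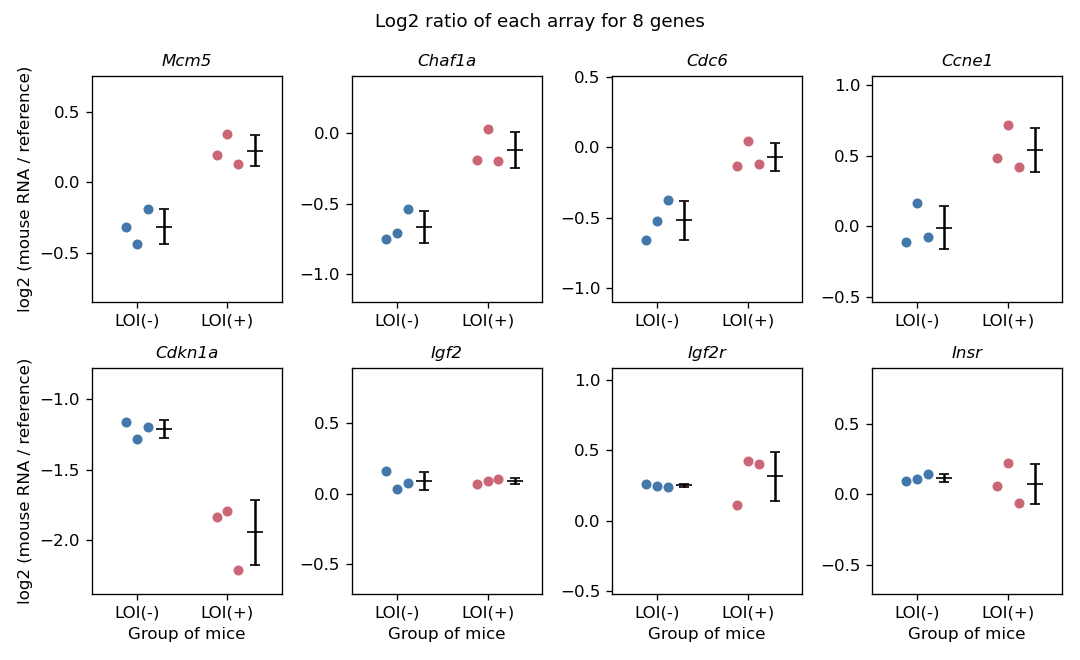
Log2 ratio of mouse RNA to reference RNA (vertical axis, the same span in each panel) on each of the 3 LOI(-) and 3 LOI(+) arrays for 8 genes, with arrays as points and the mean ± SD as a dash with its bar. The arrays of the groups lay apart for Mcm5, Chaf1a, Cdc6, Ccne1 and Cdkn1a, and overlapped for Igf2, Igf2r and Insr. Those that lay apart were picked in these data for a small p or for lack of overlap, so their separation was selected. Another Ccne1 probe had the opposite sign.

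Genes of cholesterol and fatty acid synthesis rose as a list, by 0.21 ± 0.093, with 14 of 18 higher. The list had an adjusted p of 0.00127 by camera, and with an estimated correlation the adjusted p was 0.513. Adjusted over the list alone, 7 members rose and 1 fell. The sterol enzymes Dhcr7 at 0.68 ± 0.14, Fdps at 0.69 ± 0.15 and Sqle at 0.58 ± 0.14 rose. The call was lost without LOI(+) 1, at 0.17. Genes of oxidative phosphorylation rose as a list, by 0.11 ± 0.14, with 38 of 46 higher. These genes had an adjusted p of 0.00154 by camera, and with an estimated correlation the adjusted p was 0.741. The complex I subunit Ndufa5 was at 0.29 ± 0.091, and the ATP synthase subunit Atp5e at -0.36 ± 0.13. Adjusted over the list alone 0 members passed, against 3 higher and 1 lower at an unadjusted p under 0.05. The call was lost without LOI(-) 2 and without LOI(+) 2, at 0.033 and 0.028, and the mean was 0.19 without LOI(-) 3 and 0.21 without LOI(+) 1.

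Immediate early and heat shock genes fell by 0.14 ± 0.064, with 25 of 32 lower. They had an adjusted p of 0.000373 by camera, and with an estimated correlation the adjusted p was 0.513. Klf6, a zinc finger factor induced by stress, was at -0.71 ± 0.15 and Jun, a subunit of AP-1, at 0.14 ± 0.063, and 0 members passed adjusted over the list alone, with 1 at an unadjusted p under 0.05. Without LOI(+) 1 the mean was -0.085, still called. Smooth muscle markers fell by 0.11 ± 0.073, with 10 of 13 lower. Together the markers had an adjusted p of 0.00901 by camera, and with an estimated correlation the adjusted p was 0.513. Cald1, an actin-binding protein, fell by 0.33 ± 0.070 adjusted over the list alone, though its Cy3 signal was above the negative controls on 2 of the 6 arrays, and Tagln, a smooth muscle protein, was at -0.35 ± 0.12. The smooth muscle call was lost without LOI(-) 3 and without LOI(+) 1, at -0.046 and -0.077.

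Interferon response and MHC genes fell by 0.072 ± 0.14, with 26 of 34 lower. They had an adjusted p of 0.0196 by camera, and with an estimated correlation the adjusted p was 0.680. Cd74, the chaperone of MHC class II, was at -0.41 ± 0.20 and Isg15 at -0.36 ± 0.19. The call was lost without LOI(-) 3 and without LOI(+) 1, where the mean turned to 0.019 and 0.027, and the mean was -0.12, -0.11 and -0.15 without LOI(-) 1, LOI(-) 2 and LOI(+) 2. Goblet cell markers fell by 0.076 ± 0.093, with 15 of 20 lower, but stood at 0.086 with scale normalization between arrays. As a list they had an adjusted p of 0.0290 by camera, and with an estimated correlation the adjusted p was 0.513. Muc2, the main intestinal mucin, was at -0.19 ± 0.073 and Tff3, a secreted trefoil peptide, at -0.14 ± 0.058. The goblet call was lost without LOI(-) 1, LOI(-) 3, LOI(+) 1 or LOI(+) 2, at -0.014, -0.060, -0.034 and -0.088, and the mean was -0.15 without LOI(-) 2.

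**Figure D2:**
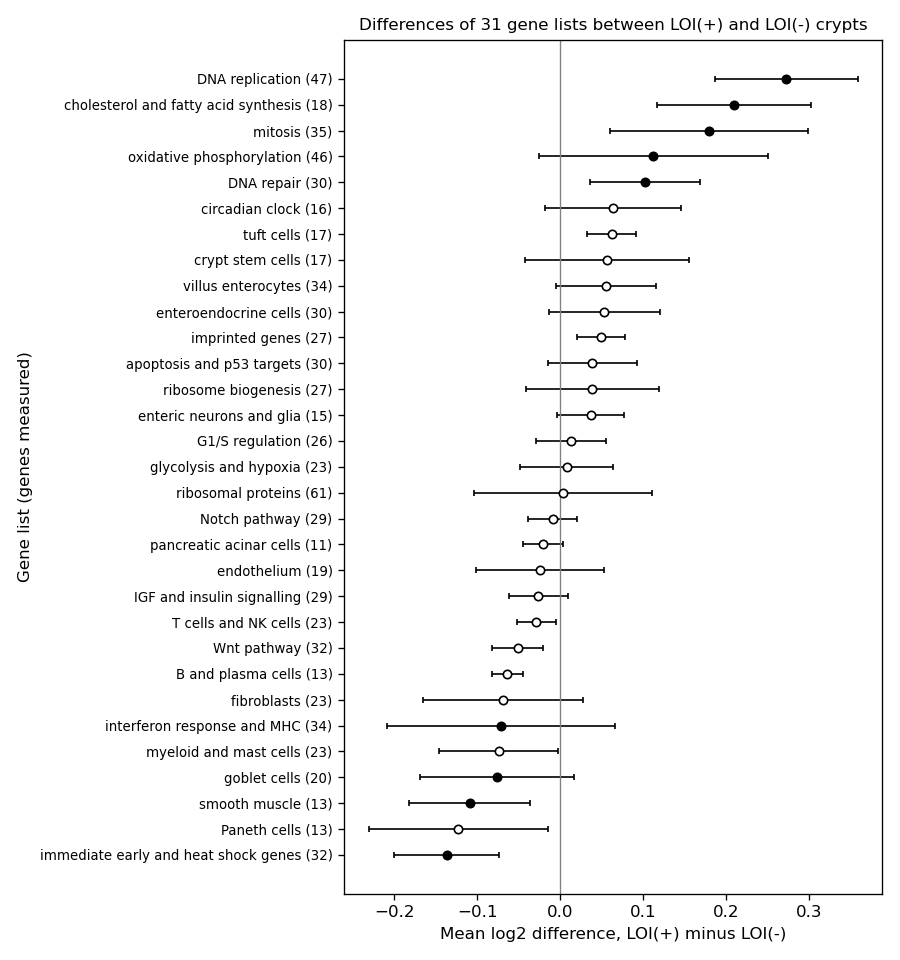
Mean log2 difference, LOI(+) minus LOI(-) (horizontal axis), of 31 gene lists with the number of genes measured in parentheses, where bars are the SE over the 3 and 3 array means and filled points are the 9 lists past an adjusted p of 0.05 by camera with a preset correlation. DNA replication lies furthest to the right at 0.27, goblet cells change sign with scale normalization, and 0 lists pass with an estimated correlation.

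Of 31 lists, 9 were called by camera with a preset correlation, 5 higher and 4 lower. The estimated correlations of these 9 were above the preset 0.01, from 0.056 in immediate early and heat shock genes to 0.60 in mitosis and 0.69 in oxidative phosphorylation, so the adjusted p with the preset correlation are too small. With an estimated correlation 0 were called, with a smallest adjusted p of 0.513, and 1 had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move on balance in a common direction, called 0, with a smallest adjusted p of 0.52 and 1 list at an unadjusted p under 0.05. Fry's test of change in either direction called 4, with adjusted p of 0.00713 for G1/S regulation, 0.0209 for villus enterocytes, 0.0209 for T and NK cells and 0.00597 for pancreatic acinar cells. The list means of the arrays lay apart between the groups in 2 of the 31 lists, DNA replication and B and plasma cells. They overlapped in every other called list.

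G1/S regulation and the other 21 lists were not called, and the means of those 21 follow with the adjusted p of camera in parentheses. Crypt stem cell markers were at 0.056 (0.671), with Smoc2 at 0.22 ± 0.12 and Bmi1 at -0.16 ± 0.075, and the stem cell mean was 0.12 without LOI(+) 2 and turned to -0.028 without LOI(+) 3. Paneth cell markers were at -0.12 (0.0966), with Nupr1 at -0.50 ± 0.20 and Mmp7, which activates defensins, at -0.16 ± 0.092. Among signalling lists, IGF and insulin signalling was at -0.027 (0.27), imprinted genes at 0.049 (0.190), the Wnt pathway at -0.051 (0.0779) and the Notch pathway at -0.0091 (0.217). The IGF list went to -0.046, -0.0013, -0.0035 and -0.044 without LOI(-) 2, LOI(-) 3, LOI(+) 1 and LOI(+) 3, and the imprinted list to 0.075 and 0.029 without LOI(+) 1 and LOI(+) 3. Among other epithelial cells, enteroendocrine cells were at 0.053 (0.409), tuft cells at 0.062 (0.217) and villus enterocytes at 0.055 (0.903). Outside the epithelium, myeloid and mast cells were at -0.074 (0.0528), fibroblasts at -0.069 (0.0804), T and NK cells at -0.029 (0.108), B and plasma cells at -0.064 (0.125), endothelium at -0.024 (0.278), enteric neurons and glia at 0.037 (0.671) and pancreatic acinar cells at -0.021 (0.217). Ribosome biogenesis was at 0.039 (0.0857), the circadian clock at 0.064 (0.964), glycolysis and hypoxia at 0.0076 (0.964), apoptosis and p53 targets at 0.039 (0.964) and ribosomal proteins at 0.0032 (0.903). The clock list holds genes that move in opposite directions when the phase shifts, so its mean cannot show whether the phase differed. Of its 16 genes 8 were higher and 8 lower, with Dbp at 0.68 ± 0.35 and Arntl at -0.27 ± 0.28. Neither Dbp nor Arntl passed over all genes tested. The median had the opposite sign to the mean for apoptosis and p53 targets and for glycolysis and hypoxia, and the test pointed down for ribosomal proteins while their mean and median were above 0. With scale normalization glycolysis and hypoxia turned to -0.090 and gained a call. Of the 22 lists that were not called, 20 changed sign, which 10 did, or moved by over 1.5 times when an array was left out. Among them villus enterocytes went to 0.0018 without LOI(-) 1 and Paneth cells to -0.025 without LOI(+) 2. Some lists gained a call. Without LOI(-) 2 these were fibroblasts at -0.13, myeloid and mast cells at -0.12, the Wnt pathway at -0.072, ribosome biogenesis at 0.068 and ribosomal proteins at -0.085. Without LOI(+) 1 it was Paneth cells at -0.20, and without LOI(+) 2 myeloid and mast cells at -0.10. Without LOI(+) 3 they were Paneth cells at -0.15, fibroblasts at -0.11, endothelium at -0.076 and the Wnt pathway at -0.073. Saturation limits the Paneth and ribosomal values. In Cy3, 5 of the 13 Paneth genes and 19 of the 61 ribosomal protein genes were saturated on some array, 4 and 6 of them on every array of a group, and in Cy5 43 of the ribosomal protein genes were. With probes saturated in either channel on any array left out, which was chosen after seeing the data, Paneth cells stood at -0.24 over 8 genes and gained a call by camera, with an adjusted p of 0.0269, and of 0.524 with an estimated correlation. That call was lost without LOI(-) 1, LOI(-) 3, LOI(+) 1 or LOI(+) 2, at -0.080, -0.19, -0.093 and -0.22, and the mean was -0.45 without LOI(-) 2 and -0.40 without LOI(+) 3. Myeloid and mast cells gained a call as well, at -0.074 with an adjusted p of 0.0482, and of 0.524 with an estimated correlation. It was lost without LOI(-) 1, LOI(-) 3, LOI(+) 1 or LOI(+) 3, at -0.032, -0.073, -0.023 and -0.097, and the mean was -0.12 without LOI(-) 2. Ribosomal proteins stood at -0.049 over 35 genes with an adjusted p of 0.374, at -0.15 with a call without LOI(-) 2, and turned to 0.055 and 0.041 without LOI(-) 3 and LOI(+) 1. Glycolysis and hypoxia stood at -0.0077 with those probes left out.

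Over single genes, 0 of 37940 genes and unnamed probes differed past an adjusted p of 0.05 in limma, where the smallest adjusted p was 0.801. At an unadjusted p under 0.05 there were 2333, against 1897 by chance, of which 1487 were higher and 846 lower in LOI(+). An unmoderated test per gene called 0 after adjustment and 2111 at that unadjusted level. Without LOI(+) 2 the count was 1495, and without LOI(-) 2 it split into 916 higher and 906 lower. The arrays of the groups did not overlap for 11.4% of genes, where chance gives 10%. The genes named next had the smallest p among named genes without overlap, and did not pass. Higher in LOI(+), beside Mcm5 and Chaf1a, were Hcfc1, a cofactor of cell cycle genes, at 0.52 ± 0.069, Cnot9 at 0.34 ± 0.050, Fads1, a fatty acid desaturase, at 0.58 ± 0.089, Ecrg4 at 0.35 ± 0.056, Gtpbp10 at 0.39 ± 0.064, Ell3 at 0.60 ± 0.10, Tiam1 at 0.47 ± 0.079 and Sh2d7 at 0.77 ± 0.13. The folate enzyme Mthfd1l at 0.47 ± 0.082 and the spindle factor Haus1 at 0.58 ± 0.10 were also among them. Lower in LOI(+), beside Cdkn1a and Cald1, were Grin2d, a glutamate receptor subunit, at -1.05 ± 0.15, Npepps at -0.39 ± 0.061, Gdpd1 at -0.54 ± 0.091, Snw1 at -0.46 ± 0.078, Arl15 at -0.35 ± 0.063, Slx4ip at -0.31 ± 0.055, Map3k6 at -0.56 ± 0.11 and Spice1 at -0.40 ± 0.083. The endotoxin receptor Tlr4 at -0.41 ± 0.077 and Xbp1, a transcription factor of secretory cells, at -0.33 ± 0.067 were also among them. The Cy3 signal was above the negative controls on 3 of the 6 arrays for Ecrg4 and on 4 of the 6 for Tlr4.

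The labels gave 4 mice as male and no sex for LOI(-) 3 and LOI(+) 2. The Y-linked gene Eif2s3y was above the negative controls on all 6 arrays, with log2 ratios from 1.04 to 2.02, and it was 1.70 in LOI(-) 3 and 2.02 in LOI(+) 2. Ddx3y, also Y-linked, lay between 0.088 and 0.51. The Y-linked Uty lay between 0.021 and 0.13, with Cy3 above the negative controls on 2 of the 6 arrays. No probe was paired with Xist, so that gene was not read.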

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

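The filters on the negative controls and on saturation, camera against every gene and probe, and the covariates for position and clock were chosen after seeing the data. In each alternative fit 0 genes passed an adjusted p of 0.05, with 1495 (without LOI(+) 2) to 3349 (without LOI(+) 1) at an unadjusted p under 0.05. In limma with every array, 0 passed an adjusted p of 0.1 and 455 an unadjusted p of 0.01. The planned filter removed 0 probes, so its alternative of no filter tested nothing. The number of lists called fell from 9 to 0 with an estimated correlation and to 0 with fry, and lay between 6 and 12 when an array was left out. The DNA replication list kept its direction in the 30 alternatives run, from 0.19 to 0.35, and its call in 28. Those calls rest on camera with the preset correlation, or on random lists that do not allow for correlated genes. For many of these alternatives the direction was fixed in advance. The array means of the replication list did not overlap, so leaving out an array could not change its sign. Several other alternatives, such as fry, rank-based camera and the replicate block, return the same mean. The list's 0.27 lost the call with an estimated correlation (adjusted p 0.513) and with fry (adjusted p 0.52), and without an array it lay between 0.23 and 0.35. Igf2 lay between -0.031 and 0.033 without an array and passed in no alternative. The replicate numbers did not pair the samples, with correlations of deviations of -0.0887, -0.249 and 0.353, and the samples numbered 3 alone correlated best with each other. With a replicate block 0 genes and 11 lists were called, with 2463 genes at an unadjusted p under 0.05, the replication list at 0.27 and Igf2 at -0.0026. Scale normalization turned goblet cells to 0.086, and glycolysis and hypoxia to -0.090 with a call. Without an array, ribosomal proteins lay between -0.085 and 0.065 and interferon response and MHC genes between -0.15 and 0.027, turning to 0.019 without LOI(-) 3 and 0.027 without LOI(+) 1. The cause of these turns was not tested. Over the other lists, 775 of 810 values kept their sign, 36 calls were lost and 35 gained. Part of the kept signs were fixed in advance, since alternatives such as fry or an estimated correlation reuse the mean of a list. Of 1819 values of named genes, 1810 kept their sign and 0 gained a call. Apart from Igf2r and Insr, these genes were picked for a small p in these data, which favours a kept sign. Where the arrays of the groups did not overlap, leaving out an array cannot change the sign. Cy3 signal near the negative controls limits genes such as Insr, Cald1, Xrcc2, Ecrg4, Tlr4, Slx4ip and Isg15.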

Other observations

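The tests on intestinal position, on nucleotide synthesis genes and on neighbours of Igf2, with their lists, were chosen after the main results were seen. Genes typical of the upper small intestine tended to be higher in LOI(+) crypts and genes of the ileum lower, and those named here did not pass the test over all genes. The lipid-binding protein Fabp1 was at 0.74 ± 0.42, the retinol carrier Rbp2 at 0.64 ± 0.37 and the apolipoprotein Apoc3 at 0.58 ± 0.17. The ileal bile acid genes Fabp6 at -0.83 ± 0.42, Slc10a2 at -0.69 ± 0.18 and Nr1h4 at -0.38 ± 0.11 lay on the other side. The Cy3 signal of Fabp6 was above the negative controls on 4 of the 6 arrays. Among hormone genes, Gip of the upper intestine was at 0.65 ± 0.26 and Cck at 0.46 ± 0.17, and Pyy of the lower intestine was at -0.60 ± 0.24. Ggt1, on the lower list, went the other way at 0.34 ± 0.23, as did Slc40a1, on the upper list, at -0.16 ± 0.17. Other members differed little. On the lower list these included the bile acid genes Fgf15 at -0.0071 ± 0.0505 and Nr0b2 at -0.025 ± 0.10. On the upper list they included Pdx1 at -0.0096 ± 0.070 and Sct at 0.0057 ± 0.18. Over 16 upper genes the mean was 0.33 and over 14 lower genes -0.24. The genes named were chosen after their values were seen.

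A hypothesis for this pattern is that the frozen pieces of the LOI(+) mice came from a slightly higher position along the intestine. It was tested on the 8 upper and 9 lower genes whose values had not been looked at when the lists were written. Their difference was 0.37 ± 0.12 (SE over genes, which are not independent replicates), in the direction the hypothesis needs. The hormone genes Gip and Pyy were its largest members on either side, in a class where Cck and Ghrl had been seen, and not counting them it was 0.25 ± 0.096. Without an array it lay between 0.30 and 0.49. An effect of the genotype on the same genes would give the same result and stays open, untested. Of the 10 splits of the arrays, 1, the real one, gave an index of upper minus lower genes as large as 0.58, with 0.52 in the highest other split, but 13 of its 30 genes were chosen after their values were seen, which favours the real split. Over the other genes the real split gave 0.37 and the highest other split 0.33, and 10 splits are too few for a share under 0.05.

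For the higher DNA replication genes in LOI(+) crypts, fewer cells of other types cannot be excluded as the cause. Goblet and Paneth cell markers, at -0.076 and -0.12, were not in the pool tested. If such cells were the smaller part of the dissections, which was not measured, their markers would have fallen by more than 0.27. The 148 pooled markers of villus enterocytes, fibroblasts, smooth muscle, endothelium, B, T and myeloid cells had a median of -0.049. Its bootstrap 95% interval ran from -0.069 to -0.027, so the measured values of this pool did not fall by that much. The background offset of 50 shrinks the differences of dim markers, such as Tie1 and Tek, so the pool can understate a fall. The medians of the arrays over the pool differed by -0.034, with a 95% interval from -0.12 to 0.049. Of the 4 brightest of these markers outside the epithelium, Lyz2 at -0.40 ± 0.19 and Tagln at -0.35 ± 0.12 went with that explanation and Aqp1 at 0.12 ± 0.14 and Nkg7 at -0.063 ± 0.072 did not. The tables argue against the ratio to the reference and the loess fit, since in the Cy3 channel alone the list stood at 0.28 ± 0.081 and in the Cy5 channel at 0.037 ± 0.024. A different clock phase at dissection cannot be told apart, because the mean of Dbp, Nr1d1, Per2, Per3 and Tef was 0.30 with a 95% interval from -0.47 to 1.06. Position along the intestine cannot be told apart either, since with the position index as a covariate the list stood at 0.27 ± 0.16, too wide to exclude a value under 0.14, though it kept its call by camera with the preset correlation, and the genotype stays open as well.

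For the replication difference, 1 of the 10 splits, the real one, gave a value as large as 0.27, with 0.25 in the highest other split, and 10 splits are too few for a share under 0.05. For genes at an unadjusted p under 0.05, 4 of 10 splits gave as many as the real 2333, with 4653 in the highest other split. The split that gave 4653 genes, LOI(-) 1, LOI(-) 2 and LOI(+) 1 against the rest, also gave the 0.25 of the replication list. For lists called by camera, 2 of 10 splits gave as many as the real 9, with 11 in the highest other split, and for both counts too the splits are too few for a share under 0.05.

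If nucleotide and one-carbon metabolism belonged to the same program as DNA replication, its genes could be higher too. The 23 genes not looked at before had a mean of 0.049, with 16 higher, and camera did not separate them from other named genes, so this stays undecided. If the deletion acted on neighbouring genes of chromosome 7, the 20 measured genes nearest to Igf2, 10 on each side, could differ as a set. Their mean was 0.021, with 9 higher, and camera did not separate them from other named genes, while Kcnq1 at 0.32 ± 0.10 was too large to exclude an effect on single neighbours.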
